A study of Mus musculus with 4 samples.

How the data were processed

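RNA of 4 mouse samples was hybridised by the authors to Agilent single-colour (Cy3) whole mouse genome arrays, 1 array per sample: mesenchymal stem cells, the tissue made from them after transfection with gene A, ligament of wild type mice and ligament of A-transgenic mice. All 4 arrays lay on the same slide and carried the same scan time. Per the file headers, each scanner file holds the spot intensity as background-subtracted and detrended processed signal on a linear scale, made by Feature Extraction 10.7.1.1, with no normalization between arrays. The submitters' notes name version 9.5.1.1, and this difference could not be settled. The deposited value table also holds linear intensity (median 49.7, 39429 probes). Its 4 columns have nearly the same sorted values, at most 0.816 from those of the stem cell column. Quantile normalization over the arrays gives such columns, although the method is not stated. Each column had its highest correlation with the scanner file of its own sample.

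Each array held 44397 spots, 43020 of them not controls. Non-uniform and population outlier spots, 155 to 281 per array, were left out, and no spot was saturated. Log2 processed signal minus the array's 75th percentile was the normalised signal, spots of a probe were averaged, and each gene was represented by its probe with the highest mean over the 4 arrays. Among genes with several probes measured on both arrays, some had probes past 2-fold in opposite directions. These were 18 of 3774 in tissue against stem cells and 1 of 2924 in transgenic against wild type ligament. They were 81 of 2701 in wild type ligament against stem cells and 104 of 2717 in tissue against wild type ligament. Probes were named by the supplied pairing of RefSeq accessions and symbols where this could be done (26761 of 39429 probes) and otherwise by the symbol in the files, which gave 30458 names. Probe positions are those of the files, whose headers name mm9. No reference genome was used and probes were not realigned.

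In each of 4 comparisons a gene was compared when it was well above background, by the scanner software's mark, on at least 1 of the arrays. Where the dimmer array was not well above background, the fold is a bound against the higher of the probe's own signal and the lowest well-above-background signal of that array, written as at least N-fold. A gene is called higher or lower from 2-fold. With 1 array per group no test between groups was possible and none was made. For 39 gene lists the median log2 difference was set against 10000 random lists of the same size, drawn from 20 bins of mean signal. This made 156 list medians, so about 1 in 20 lying in the outer 5% of random lists would be no surprise even for lists of unrelated genes. Random lists draw genes independently, whereas genes of a list can vary together. More lists than this can therefore lie there without any effect of A. The percentiles describe the arrays and are not p-values. The lists covered collagens, tendon and periodontal ligament, proteoglycans, elastic fibre, collagen processing, matricellular, basement membrane, metalloproteinase and stromal genes, markers of cartilage, bone, fat, skeletal and smooth muscle, endothelium, macrophages, lymphoid, neutrophil and erythroid cells, epidermis and nerve. They also covered cell cycle, immediate early, heat shock, unfolded protein, interferon, antigen presentation, glycolysis, oxidative phosphorylation, cholesterol, TGF-beta, Wnt, Hox, imprinted, pluripotency, chemokine and sex-linked genes.

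The lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 8 highest and 8 lowest log2 differences among genes measured on both arrays with an official-style symbol. It also took the 4 largest bounds in each direction, all members of the tendon and ligament, fibrillar collagen and proteoglycan lists, up to 4 members of every other list with the largest difference, and up to 6 genes per direction for the overlap. Genes were named from this set.

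The share of genes nearer to wild type ligament compared the absolute distance of the tissue and of stem cells from ligament. Ligament-high genes were at least 4-fold higher in both ligaments than in stem cells. Shares carry exact Clopper-Pearson 95% intervals, which treat genes as independent. The shared stem cell array was examined with 100 simulations of an unchanged tissue with the spot noise of the arrays. Spot noise was the pooled SD over probes with 10 spots. Only probes whose kept spots were all well above background entered, 230 to 249 of 399 per array. The number of arrays limits the precision of every value.

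Alternatives changed 1 choice at a time: normexp background correction of raw spot and local background signal with offset 50 (limma 3.58.1 in R 4.3.3), quantile normalization, centring on probes detected on all arrays, the deposited value table, only genes well above background on every array compared, no filter and no bound, the mean of all probes of a gene, a 4-fold threshold, an 8-fold definition of ligament-high genes and transgenic ligament as the reference. Random lists under alternatives numbered 1000. The steps were tested on simulated data with 200 changed genes among 30419. At a true 1.5-fold change 4.00% were called, at 2.5-fold 94.0% and from 4-fold 100.0%, with no unchanged gene called. The simulated arrays differed only by spot noise beside the set changes and had the same detection marks. These shares therefore leave out the spread of cultures, animals and labelling and the rule for bounds, and are no error rate of the calls. A shifted list lay at percentile 100 and an unshifted list at 14.7. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.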

Results

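Gene expression was measured in 4 mouse RNA samples, 1 array each, on an Agilent whole-genome microarray read in a single colour (Cy3). The first sample was mesenchymal stem cells, the multipotent precursors of connective tissue, taken from embryos of the C3H background. The ligament-like tissue came from these cells after transfection with a plasmid carrying a mouse gene that the labels call only A, in pCAGGS, a vector for strong expression in mammalian cells; it is called the transfected tissue here. The remaining samples were ligament of wild type mice and ligament of mice transgenic for A, both of the C57BL/6J background. The design asks whether gene A turns stem cells towards ligament, and how alike the matrix of the tissue and of ligament are. Each group held 1 array, so no difference below has a replicate check or a p-value, and strain and origin differ together whenever cells are set against ligament.

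Between 49.0% and 56.3% of the probe spots of an array were well above background. The 75th percentile of the background-subtracted signal was 1165 in stem cells, 2272 in the transfected tissue, 285 in wild type ligament and 303 in transgenic ligament. The 100 brightest spots held 12.2%, 10.1%, 23.4% and 22.4% of all signal in the same order. The SD of log2 signal over the 10 spots of a repeated probe was 0.185 in stem cells, 0.107 in transgenic ligament, 0.0992 in wild type ligament and 0.0655 in the transfected tissue. These SDs cover spot noise within an array at probes well above background, and not that of dimmer probes. They also leave out the spread between cultures or animals, which these arrays cannot give. A gene is called higher or lower when it differed at least 2-fold, and each gene list is described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size and signal level.

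The transfected tissue lay close to the stem cells it came from and far from ligament. Across 19952 genes well above background on at least 1 array, the Pearson correlation of log2 signal was 0.948 between stem cells and the transfected tissue and 0.960 between the ligaments, while the 4 pairs of a cell array with a ligament array lay between 0.712 and 0.723. Over 93 genes of the matrix lists (collagens, proteoglycans, elastic fibre, matricellular and basement membrane genes), the correlation with wild type ligament was 0.485 for stem cells and 0.567 for the transfected tissue, against 0.919 between stem cells and the tissue. Genes are not independent replicates, so these correlations only describe the arrays. Those over all detected genes include muscle, blood and skin genes, which were far higher on the ligament arrays than on the cell arrays. The distance from ligament is therefore not one of ligament genes alone.

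The comparison of the transfected tissue with stem cells asks what accompanied the introduction of A and the formation of the tissue. Genes of cell division were lower in the tissue, and genes of fat cells, of the interferon response and of some matrix proteoglycans were higher. Of 30 cell cycle genes, 27 were lower and none higher, with a median log2 difference of -2.87 and quartiles of -3.24 and -2.17, below all random lists. Birc5, an inhibitor of apoptosis needed for chromosome segregation, was lower by a log2 difference of -3.54, and the mitotic activator Cdc20 and cyclin Ccna2 differed by -3.53 and -3.47. The adipocyte list had 8 of 14 detected genes higher and none lower (median 1.91, or 1.17 with dim genes at their bound). Over the 7 genes well above background on both arrays this median fell to 0.60, at percentile 97.55. Complement factor D, Cfd, was at least 52.6-fold higher, the adipokine Adipoq at least 22.2-fold and the lipid droplet protein Plin1 at least 16.5-fold, all against stem cell signals not well above background.

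Interferon response genes had 11 of 20 detected members higher in the tissue and none lower, with a median of 1.04 at percentile 100, or 0.59 with normexp background correction. Ifi44 was 7.58-fold and Ifit1 5.26-fold higher. The unfolded protein response list had a median of 0.34 (4 of 18 genes higher, none lower, percentile 99.9), led by the stress transcription factor Ddit3 at 2.22. The immediate early list had a median of 0.29 at percentile 95.04, or 99 with quantile normalization, and Atf3 was 6.83-fold higher. Cholesterol synthesis genes had 7 of 18 lower and none higher (median -0.82, percentile 0.01), among them Cyp51 at -1.45. The hypoxia and glycolysis list had 7 of 20 lower and 1 higher (median -0.76, percentile 1.17, or -0.28 with the deposited values), with the carbonic anhydrase Car9 at -4.22 and Ankrd37 at -4.19.

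Matrix genes moved in both directions in the transfected tissue. The small leucine-rich proteoglycans, which bind collagen fibrils, had 4 of 12 genes higher and 2 lower, with a median of 0.44 at percentile 98.6, or 94.8 over genes well above background on both arrays. Lumican (Lum, probe at chromosome 10, 97035210 to 97035269, mm9) was 28.9-fold higher, epiphycan (Epyc) 21.3-fold and decorin (Dcn) 6.80-fold, and keratocan (Kera) was at least 5.95-fold higher. Podn was lower by a log2 difference of -3.55 and Prelp by -1.02, while Bgn (-0.67), Aspn (-0.72), Ogn (0.39), Omd (0.49), Ecm2 (0.83) and Fmod (-0.06) lay within 2-fold. Of 19 basement membrane genes, 8 were higher and none lower (median 0.41, percentile 98.8, or 95.8 at least under another setting), with the laminin chain Lama2 at 4.17 and Lama1 at 2.79. Of 16 elastic fibre genes, 7 were lower, elastin (Eln) at -1.82 among them, and 1 was higher (median -0.79, percentile 0.26). Collagen processing and crosslinking enzymes had 6 of 23 lower and 1 higher (median -0.58, percentile 1.26, or 8.85 with the mean of all probes and a median of -0.31 with the deposited values), with lysyl oxidase (Lox) at -1.62. Matricellular genes had 4 higher and 6 lower of 22 (median -0.54, percentile 5.08), from Sparcl1 at 3.38 to Smoc1 at -3.28.

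Fibrillar collagens had none of 10 genes higher and 3 lower, Col1a1 at -1.07, Col2a1 at -1.03 and Col5a1 at -1.26. Their median of -0.24 lay among the random lists (percentile 56.8) and turned to 0.12 with quantile normalization. Col1a2 (-0.17), Col3a1 (-0.30), Col5a2 (0.00), Col5a3 (-0.58), Col11a1 (0.24), Col11a2 (0.63) and Col27a1 (0.48) lay within 2-fold. Of 17 detected tendon and ligament genes, Kera was higher and 3 were lower. These were the collagen receptor Itga11 (-3.19), the tendon transcription factor Scx (-1.74) and tenascin C (Tnc, at least 4.86-fold). Tenomodulin (Tnmd, -0.65), Mkx (0.03), Comp (0.03), Fmod (-0.06), Egr1 (0.29), Egr2 (0.78), Six2 (-0.77), Eya1 (-0.81), Fbn2 (-0.72) and Gdf6 (0.09) were within 2-fold, as were the bounds for Thbs4 and Gdf5. The list's median of -0.65 lay at percentile 1.12, but it was -0.06 at percentile 41.8 over the 13 genes well above background on both arrays and -0.22 with the mean of all probes. TGF-beta target genes had 7 of 17 lower and none higher (median -0.52, percentile 1.68), among them Inhba at -2.70. Mesenchymal stromal markers had 4 of 15 lower and none higher (median -0.74, percentile 0.38), with Alcam at -2.47 and Cd44 at -2.04.

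In all, 1977 genes were higher and 2350 lower in the tissue, 24.2% of the 17898 genes with a value. Of these, 479 higher and 527 lower genes have only a bound. With normexp background correction the counts were 1075 and 2171, with quantile normalization 1974 and 1972, and with the deposited values 2052 and 2004, so the excess of lower genes depended on the processing. The highest gene measured on both arrays was the glutathione transferase Gsta3 (probe at chromosome 1, 21255189 to 21255248, mm9), 54.3-fold higher, and the next highest outside the proteoglycans were the peptide transporter Slc15a2 (40.4-fold), the lysophospholipase Enpp2 (40.3-fold), Cib3 (34.2-fold), the methyltransferase Inmt (31.6-fold), Gsta1 (30.1-fold) and the carboxylesterase Ces1a (28.6-fold). Gsta family members have near-identical sequences and their probes may not tell them apart. Among genes not well above background in stem cells, Itih4 was at least 88.0-fold and Mlana at least 42.4-fold higher. Among the lowest were Anxa8 (-5.50), the interleukin 33 receptor Il1rl1 (-4.98), Col28a1 (-4.95), Serpina3g (-4.69) and the histone genes H1f5 (-4.69) and H2ac4 (-4.51). The skeletal muscle list had none of 15 detected genes higher and 6 lower (median -1.04), and the macrophage list none of 10 higher and 5 lower (median -0.99). These medians were -0.24 and -0.46 with no filter and no bound.

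**Figure D1:**
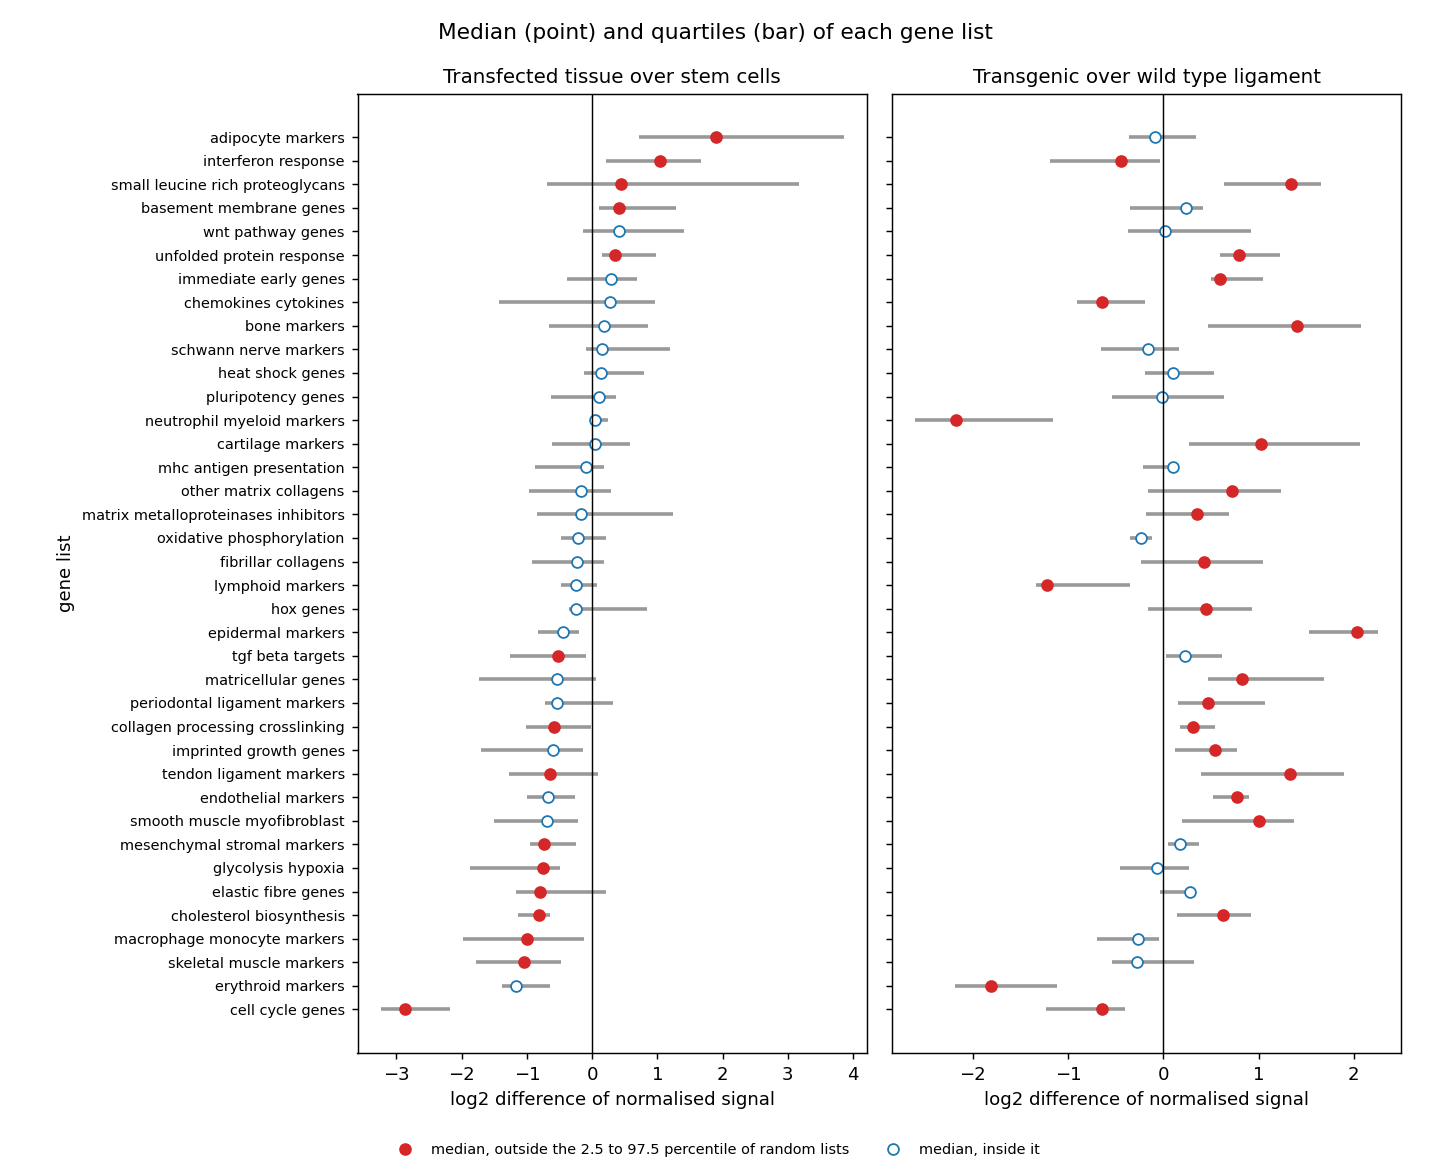
Median log2 difference of normalised signal (points) with quartiles (bars) for the detected genes of each list, in transfected tissue over stem cells (left) and transgenic over wild type ligament (right), 1 array per group. Filled points lie in the lowest or highest 2.5% of random lists; the cell cycle list is lowest on the left at -2.87, and the neutrophil list (-2.17) and epidermal list (2.03) mark the ends on the right.

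Transgenic ligament was compared with wild type ligament to ask what the introduced gene does in the animal. Genes of tendon, proteoglycans, cartilage, bone and skin were higher on the transgenic array, and genes of granulocytes, red cells and lymphocytes were lower. Some lists share genes, so their medians are not separate observations. Fmod, Kera and Chad are in both the tendon and the proteoglycan list, and Egr1 and Egr2 in both the tendon and the immediate early list. Comp is also in the matricellular and cartilage lists, and Thbs4 in the matricellular list. Of 19 detected tendon and ligament genes, 9 were higher and 1 lower, with a median of 1.33, above all random lists, or 0.74 with dim genes at their bound and 0.46 with normexp background correction. The matrix protein Comp (probe from chromosome 8, 72905692 to 72905825, mm9) was 5.96-fold higher, Tnmd 5.46-fold, fibromodulin (Fmod) 4.42-fold and thrombospondin 4 (Thbs4) 4.01-fold. Egr1 (1.79), Chad (1.52), Kera (1.43), Egr2 (1.33) and Scx (1.07) made up the rest of the higher genes, and the growth factor Gdf7 was at least 7.10-fold lower. Tnc (0.74), Eya2 (0.51), Itga11 (0.28), Six2 (-0.25) and Eya1 (-0.42) lay within 2-fold. Of 12 small leucine-rich proteoglycans, 7 were higher and none lower (median 1.34), with Fmod, Aspn (2.13), Chad, Ogn (1.44), Kera, Ecm2 (1.25) and Omd (1.18) past 2-fold, and Lum (0.73), Dcn (0.36), Podn (0.20) and Bgn (-0.26) within it.

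The other matrix lists also had positive medians, but elastic fibre genes (0.28, percentile 97.1) and basement membrane genes (0.24, percentile 94.0) lay within the central 95% of random lists. Of 21 matricellular genes, 9 were higher and none lower (median 0.82), and 3 of 11 other matrix collagens were higher (median 0.72, percentile 99.9, or 0.34 at percentile 94.6 with the mean of all probes), Col8a2 at 2.11 among them. Of 10 fibrillar collagens, Col2a1 (2.15), Col11a2 (1.06) and Col1a2 (1.01) were higher and none lower, with a median of 0.43 at percentile 99.3. Col1a1 was at -0.53, Col5a3 at -0.51, Col11a1 at -0.31, Col5a1 at 0.00, Col3a1 at 0.39 and Col5a2 at 0.47. The collagen processing list had a median of 0.31 (2 of 22 higher, percentile 99.3), led by Lox at 2.04. Bone markers had 6 of 11 higher (median 1.41), including Mepe (2.76), Bglap2 (2.21) and Phex (2.09), and cartilage markers 5 of 13 (median 1.03, or 0.72 with dim genes at their bound), with none lower in either. Smooth muscle and myofibroblast genes had 6 of 12 higher (median 1.01, or 0.76 with dim genes at their bound) and endothelial genes 2 of 15 (median 0.77), again with none lower. With normexp background correction the cartilage, smooth muscle and endothelial medians fell to 0.38, 0.37 and 0.35, still in the highest 2.5% of random lists. The highest gene was Cilp, a cartilage matrix protein (probe at chromosome 9, 65128007 to 65128066, mm9), at 21.6-fold; others among the 8 highest were the cornified envelope gene Lce1a1 (12.1-fold), Mss51 (10.3-fold), Cytl1 (7.96-fold) and loricrin (Lor, 7.83-fold).

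Of 15 epidermal genes, 11 were higher on the transgenic array and none lower (median 2.03), with the keratins Krt1 at 2.37 and Krt14 at 2.27. The Lce1 genes are near-identical copies and their probes may share signal. In the opposite direction, 12 of 14 neutrophil and myeloid genes were lower and none higher (median -2.17), with lactoferrin (Ltf) at -2.98 and Retnlg at -2.92. Of 9 erythroid genes, 7 were lower (median -1.81), with the haemoglobin genes Hba-a1 at -2.27 and Hbb-b2 at -2.15, and 7 of 12 lymphoid genes (median -1.22, or -0.69 with normexp), with Cd79b at -1.99. Among the 8 lowest genes were the eosinophil granule genes Prg2 (-5.19, probe at chromosome 2, 84822799 to 84822858, mm9), Ear1 (-4.63) and Rnase2a (-4.22), and the cardiac actin Actc1 (-4.37). Ear family members are also near-identical. The mast cell protease gene Tpsab1 was at least 29.0-fold lower. Skeletal muscle genes had 3 higher and 2 lower of 24 (median -0.28, percentile 27.5), from Myh7 at 1.71 to Mylpf at -2.06, and adipocyte genes none higher and 2 lower of 15 (median -0.09, or 0.04 at most under another scaling). Any gene named in this comparison that blood, marrow, skin or muscle also expresses carries these differences with it.

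Unfolded protein response genes had 8 of 18 higher and none lower (median 0.79), led by Sdf2l1 (1.49), Trib3 (1.47) and the chaperone Hspa5 (1.44). Immediate early genes had 3 of 16 higher (median 0.60, percentile 99.98), Atf3 at 2.40 first among them, and cholesterol synthesis genes 2 of 17 (median 0.63, percentile 99.8, or 0.47 with dim genes at their bound and 0.27 with normexp), with Sqle at 1.16. Cell cycle genes had 9 of 26 lower and 1 higher (median -0.64), interferon response genes 6 of 16 lower and none higher (median -0.44, percentile 0.62, or 3.90 at most under another setting), and chemokines and cytokines 1 of 9 lower (median -0.64, percentile 0.60). Altogether 1018 genes were higher and 1179 lower, 13.4% of 16409 with a value. The counts were 408 and 570 with normexp background correction, and 669 and 804 over genes well above background on both arrays.

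**Figure D2:**
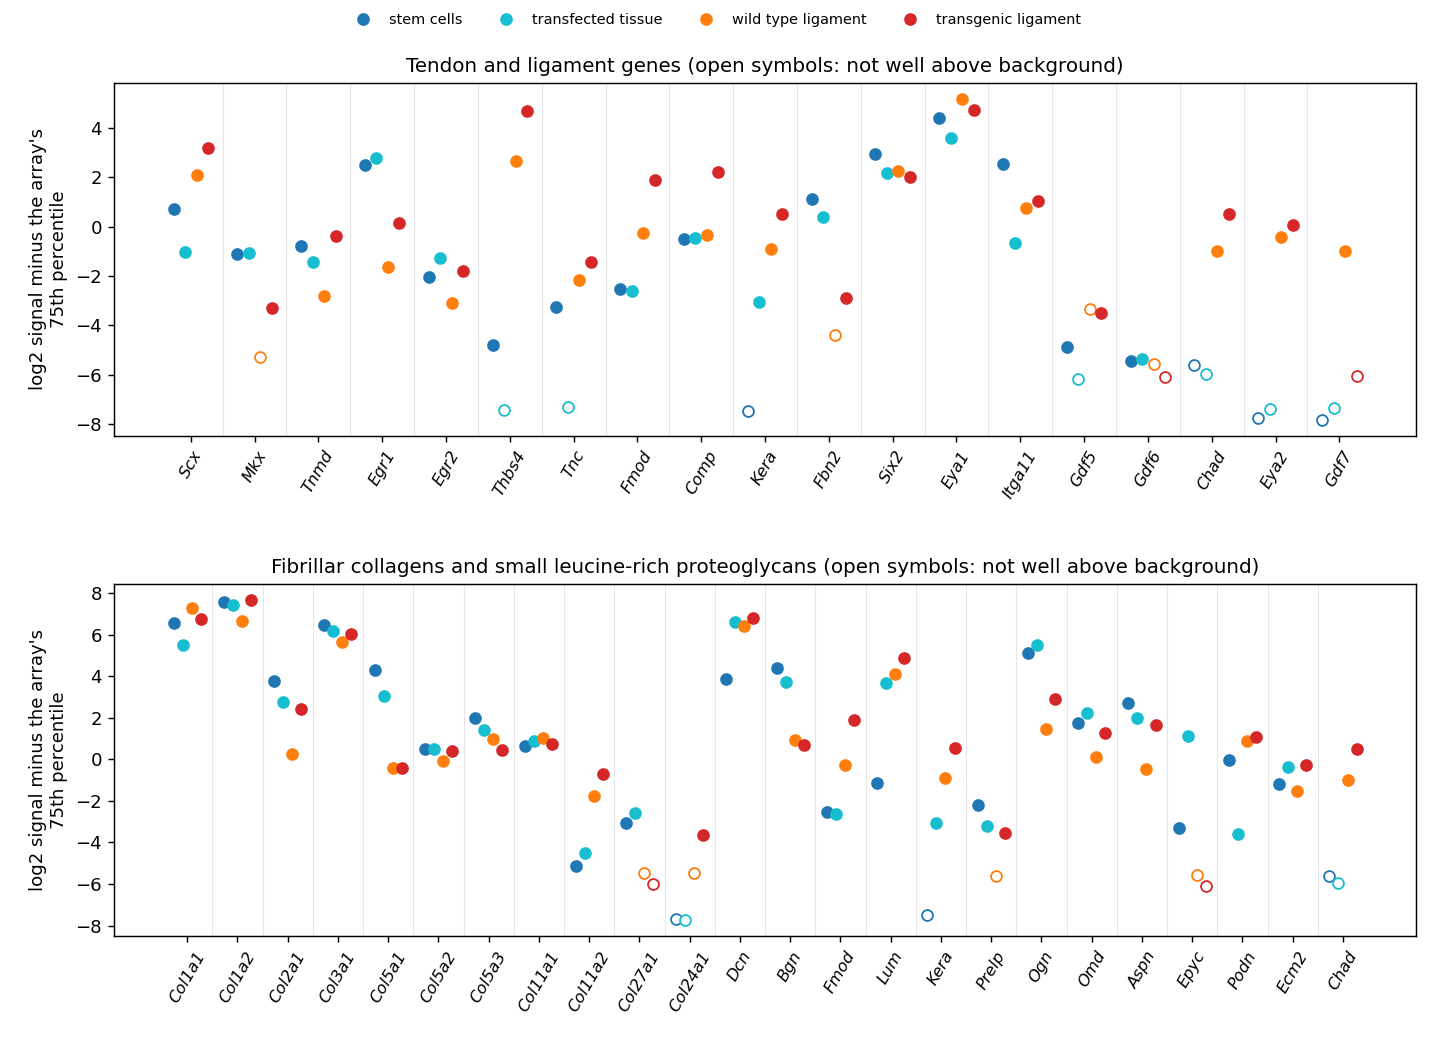
Log2 signal minus the array's 75th percentile for genes of the tendon and ligament list, 1 of them not drawn (top) and for fibrillar collagens and small leucine-rich proteoglycans (bottom), 1 point per gene and array, open where the signal was not well above background. Lum stands at -1.15 in stem cells and 3.70 in the transfected tissue, near its 4.12 in wild type ligament, whereas Thbs4 and Chad are not well above background in the tissue.

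Wild type ligament was set against stem cells as the reference for what a ligament profile is. Genes of skeletal muscle and blood had the largest list medians. All 24 skeletal muscle genes were higher in ligament, with a median of 12.90, or 11.98 with dim genes at their bound. The fast-muscle troponin Tnnc2 differed by 15.41 and Tnnt3 by 14.85, and Myh8 had the largest bound, at 16.25. All 14 neutrophil genes were higher (median 9.02), as were all 9 detected erythroid genes (8.29), all 11 lymphoid genes (5.93) and all 13 epidermal genes (5.86). Many of these genes were not well above background in stem cells, and with dim genes at their bound the neutrophil, lymphoid and epidermal medians were 7.58, 4.57 and 4.52. Over genes well above background on both arrays the lymphoid median was 2.58, at percentile 97.0, and the neutrophil median 5.45, and with normexp the epidermal median was 3.22. Macrophage genes had 14 of 15 higher (4.92), adipocyte genes 13 of 15 (5.34), with medians of 2.99 and 2.63 over genes well above background on both arrays, endothelial genes 10 of 14 (2.69) and oxidative phosphorylation genes 19 of 20 (2.66, or 1.69 with the deposited values). Lower in ligament were 27 of 30 cell cycle genes (median -3.47), 18 of 23 collagen processing genes (-2.65), 17 of 18 cholesterol synthesis genes (-3.52), all with none higher, 13 of 17 elastic fibre genes (-3.13, 4 higher) and 11 of 18 unfolded protein response genes (-1.93, 2 higher). Basement membrane genes were divided, with 6 higher and 8 lower of 19 (median -0.92, percentile 6.40).

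Tendon and ligament genes were divided between the cells and ligament. Of 20, 8 were higher in wild type ligament and 6 lower (median 0.52, percentile 71.4). Thbs4 (7.46), Fmod (2.29), Scx (1.37) and Tnc (1.09) were higher on both-array values, and Eya2, Kera and Chad had bounds of 5.19, 4.72 and 4.60. Egr1 (-4.14), Tnmd (-2.02), Itga11 (-1.79) and Egr2 (-1.07) were lower, as were Fbn2 and Mkx by bounds of -4.43 and -2.22; the value of Egr2 was 0.05 with normexp background correction. Comp (0.13), Eya1 (0.76) and Six2 (-0.68) lay within 2-fold. Fibrillar collagens had 1 of 10 higher, Col11a2 at 3.38, and 2 lower, Col5a1 at -4.69 and Col2a1 at -3.49 (percentile 3.37 for the list), while Col1a1 (0.72), Col1a2 (-0.90) and Col3a1 (-0.82) were within 2-fold. Of 13 small leucine-rich proteoglycans, 5 were higher, Lum at 5.28 and Dcn at 2.56 among them, and 5 lower, with Ogn at -3.64, Bgn at -3.47, Aspn at -3.18 and Omd at -1.65 (percentile 26.8 for the list). Over all genes, 6070 were higher and 4313 lower, 62.3% of 16660. Quantile normalization gave 5282 and 5305 and the deposited values 5289 and 5339, without the excess of higher genes. The lowest were Ptx3 (-8.02), Ccn5 (-7.53), the growth factor Ptn (-7.38) and Ccnd1 (-7.11), and Rspo2 had the lowest bound, -8.50.

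The transfected tissue was compared directly with wild type ligament to ask how near its matrix came. Muscle, blood and skin genes were absent from the higher side: none of 24 skeletal muscle, 14 neutrophil, 9 erythroid, 11 lymphoid or 13 epidermal genes was higher in the tissue. Their medians were -13.40, -9.29, -9.80, -5.68 and -6.42, or -11.90, -8.22, -8.47, -4.49 and -4.44 with dim genes at their bound. The weakest medians over all settings were -10.77 for muscle, -6.32 for neutrophil, -3.41 for lymphoid and -3.73 for epidermal genes. Only 2 erythroid genes were well above background on both arrays, and their median was -2.84 at percentile 6.00. Tendon and ligament genes had 5 of 19 higher and 10 lower (median -1.41, percentile 2.71, or -0.10 at percentile 46.8 over the 11 genes well above background on both arrays). Thbs4 had a bound of -8.21, Tnc one of -3.37 and Chad one of -4.54, and Scx (-3.11), Fmod (-2.35), Kera (-2.15), Eya1 (-1.57) and Itga11 (-1.41) were lower, while Egr1 (4.42), Egr2 (1.85) and Tnmd (1.37) were higher. Comp (-0.10) and Six2 (-0.09) matched within 2-fold. Of the fibrillar collagens, Col5a1 (3.43) and Col2a1 (2.46) were higher and Col11a2 (-2.75) and Col1a1 (-1.79) lower, and Col1a2 (0.73), Col3a1 (0.52) and Col5a2 (0.61) were within 2-fold. Of 13 small leucine-rich proteoglycans, 6 were higher and 4 lower (median 1.14, or 0.205 with dim genes at their bound). Lum (-0.42) and Dcn (0.20) lay within 2-fold of ligament. Epyc, Ogn (4.03), Bgn (2.80), Aspn (2.46) and Omd (2.14) were among the higher genes. The lower genes were Podn (-4.47) and, as given above, Fmod, Kera and Chad.

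Other lists were higher in the tissue than in ligament. Collagen processing genes had 18 of 23 higher and none lower (median 1.78), with Loxl1 at 5.06 and Lox at 4.63. Elastic fibre genes had 13 of 17 higher and 4 lower (2.59), periodontal ligament markers 6 of 10 higher and 2 lower (2.40, or 1.104 with normexp background correction), metalloproteinases and their inhibitors 11 of 18 higher and 5 lower (3.22, or 0.63 with no filter and no bound), and cholesterol synthesis genes 15 of 18 higher and none lower (2.99, or 1.75 with normexp). Altogether 4040 genes were higher and 6302 lower, a share of 39.1% higher. With quantile normalization the counts were 5176 and 5106, or 50.3% higher. It moved the median over genes well above background on both arrays by 0.41. The deposited value table gave 50.5%, so the split between directions depended on the scaling. Ptn (8.01), Lurap1l (6.92), Ccn5 (6.69) and Gas1 (6.57) were the highest genes on both-array values, and Tnnc2 (-15.14), Pvalb (-14.86) and Tnni2 (-14.80) the lowest.

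Whether the tissue had moved from stem cells towards ligament was measured in 2 ways. Of 3034 genes at least 4-fold higher in both ligaments than in stem cells, 504 were at least 2-fold higher in the transfected tissue (16.6%, 95% exact binomial interval 15.3% to 17.98%) and 190 were lower (6.26%). Random genes of the same signal gave 9.12% higher and 10.1% lower. Of the 3034 genes, 1747 were well above background in stem cells, and by the rule the others could not be called lower. Random genes were matched on signal and not on this mark, so the low share of lower genes partly follows from the choice of the set. Of 1629 genes at least 4-fold lower in both ligaments, 513 were lower in the tissue (31.5%, against 11.2% of random genes) and 76 higher (4.67%). The ligament-high genes also take in muscle, blood and skin genes, and the ligament-low genes take in cell cycle genes. These shares therefore do not measure ligament character alone. Both differences use the same stem cell array, which ties them together. The Pearson correlation of tissue minus stem with wild type ligament minus stem across 13169 genes was 0.284, where a simulated unchanged tissue gave 0.0847 from spot noise alone, and the covariance was 0.522 against 0.034. Spot noise leaves out the noise of culture and labelling, so the simulation does not cover all that the shared array can add.

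Over all 19331 detected genes, 49.2% were nearer to wild type ligament in the tissue than in stem cells. The share was 93.3% of 30 cell cycle genes (28 genes, percentile 100), 94.4% of 18 cholesterol synthesis genes, 80.0% of 15 adipocyte genes (percentile 98.9) and 78.3% of 23 collagen processing genes (percentile 99.6). It was 26.3% for immediate early genes, 5 of 19 (percentile 1.73). The shares of 23.8% of 21 glycolysis and hypoxia genes, where matched random lists gave 40.9%, and 31.8% of 22 interferon response genes lay within the central 95% of random lists (percentiles 4.98 and 5.00). For the matrix lists pooled it was 54 of 92 genes, 58.7% (exact interval 47.9% to 68.9%, percentile 96.5), or 51.1% with quantile normalization, and this pooling was not part of the design. For tendon and ligament genes it was 9 of 20, or 45.0% (percentile 33.2), and for small leucine-rich proteoglycans 6 of 13, or 46.2% (percentile 46.4).

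The tissue against stem cells and the transgenic against wild type ligament share no array, and A was introduced in both. Of 14522 genes with a value in both comparisons, 114 were higher in both, where independent lists would share 65.5, and 172 were lower in both, against 83.3. Genes moving in opposite directions were also more frequent than independent lists give, 116 against 68.0 for those higher in the tissue and lower in transgenic ligament and 142 against 80.1 for the reverse. Across 13036 genes well above background on all arrays the 2 differences correlated at 0.075. Ucma, Atf3, Aloxe3, Phex, Gsta2 and Kif27 led the genes higher in both, with Atf3 at 2.77 and 2.40 and Phex at 3.25 and 2.09. Wfdc18, Slpi, Zfp558, Adam8, Ltf and Alox5ap led those lower in both, with Slpi at -3.40 and -2.78 and Adam8 at -3.94 and -2.30.

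**Figure D3:**
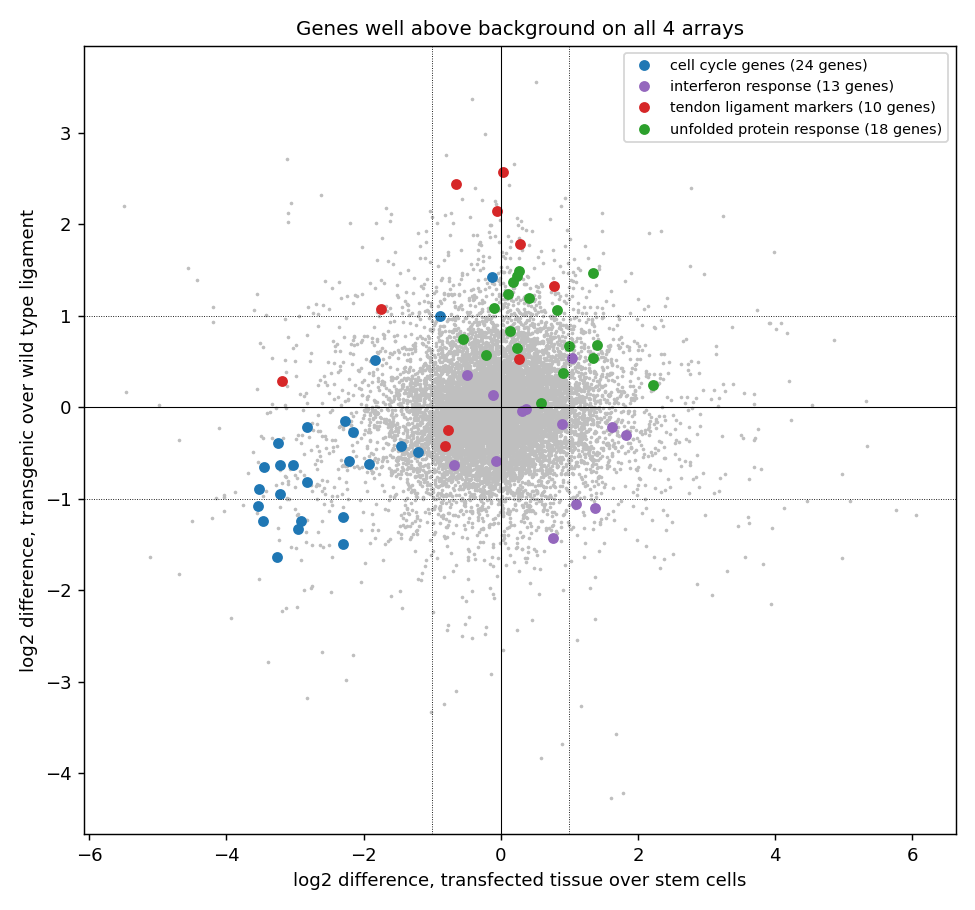
Log2 difference of transfected tissue over stem cells (horizontal) against transgenic over wild type ligament (vertical) for the 13036 genes well above background on all 4 arrays, with dotted lines at 2-fold and 4 gene lists in colour. Cell cycle genes lie to the left, tendon and ligament genes mostly above 0, and the correlation over all genes is 0.075.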

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

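All tests of explanations in this part were chosen after the result was seen. A set of 4 gene lists lay in the outer tails of random lists in opposite directions in the transfected tissue against stem cells and in transgenic against wild type ligament, and the difference between the comparisons was not tested for any of them. Cholesterol synthesis genes had a median log2 difference of -0.82 in the tissue and 0.63 in transgenic ligament, which fell to 0.27 with normexp, and collagen processing genes had -0.58 and 0.31. Interferon response genes had 1.04 and -0.44, and tendon and ligament genes -0.65 and 1.33. For the tendon list the tissue value was -0.06 over genes well above background on both arrays. The cell cycle, unfolded protein response and small leucine-rich proteoglycan lists instead lay in the same outer tail in both comparisons. Outside the measured genes, the 75th percentile signal over the median signal of the added control RNAs was 3.00 in the transfected tissue, against 1.38 in stem cells, 0.234 in wild type ligament and 0.131 in transgenic ligament. This ratio was not used to scale the arrays. Between arrays it differed by a factor of 2.172 for tissue over stem cells and 0.559 for transgenic over wild type ligament. For wild type ligament over stem cells the factor was 0.169, and for tissue over wild type ligament 12.821. Scaling by it would shift all genes of a comparison alike and leave places among random lists unchanged. Signs of smaller list medians and the counts of higher and lower genes could change, and were not recomputed.

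Skeletal muscle, blood and marrow genes stood far above the stem cells on the ligament arrays. The scalings tried were argued against, since the lowest median of the muscle list over all settings was 10.02. Scaling to the added control RNAs was not among them. Their ratio of 0.169 for wild type ligament over stem cells would lower the median but leave it positive. RNA of muscle, blood and marrow in the dissected tissue stays open as a candidate source. The share of muscle, neutrophil and erythroid genes both well above background in wild type ligament and higher than in stem cells, 47 of 48 (97.9%), restates the pattern and decides nothing. Acta1, among the most abundant muscle transcripts, had a normalised log2 signal of 10.48 in wild type ligament and 0.85 in stem cells. No biological explanation was tested.

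Skin genes were higher and blood and marrow genes lower in transgenic than in wild type ligament, beside higher tendon and proteoglycan genes. A lower share of blood and marrow cells alone was argued against, because it would raise all other cell types alike, and the epidermal median exceeded the muscle median by 2.31 where random lists had an SD of 0.182. Different amounts of skin, blood and marrow in the dissections stay open: that 46 of 50 genes (92%) moved with their list restates the pattern and decides nothing. The bone, cartilage, smooth muscle and endothelial medians were positive too, at 1.41, 1.03, 1.01 and 0.77. The makeup of the dissections was not tested for these lists or for the tendon and proteoglycan genes, and stays open for them as well. For the tendon and ligament list, the scalings tried were argued against: the lowest median over all settings was 0.46, and each lay at percentile 100. Scaling to the added control RNAs was not among them. By those RNAs the signal ratio of transgenic to wild type ligament was 0.559, which would lower the median. Such a shift of all genes alike leaves the place among random lists unchanged, but the sign of the median is not settled. An effect of the transgene on any of these lists stays open and untested, as each genotype had 1 array.

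Cell cycle genes were lower and adipocyte genes higher in the transfected tissue than in stem cells. The scalings tried were argued against for the cell cycle list, whose highest median over all settings was -2.44. Scaling to the added control RNAs was not among them. Their ratio of 2.172 for tissue over stem cells would raise the median but leave it negative. RNA of the ligament dissections was argued against as the source of the adipocyte genes, because the muscle median lay below the adipocyte median by more than such RNA allows, a difference of -8.22 with an SD of 0.705. Time in culture or cell density cannot be told apart from the introduced gene for the cell cycle median of -2.87, since no untransfected culture of the same age is among the arrays. A response to A stays open on the same ground.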

How the results depend on the processing

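No paired analysis was possible because each group held a single array, numbered 1. All alternatives here were set before any value was computed. Of the lists in the outer 2.5% on either side of random lists, 10 of 15 stayed there in all 8 settings for the tissue against stem cells, 19 of 24 for transgenic against wild type ligament, 19 of 25 for wild type ligament against stem cells and 20 of 25 for the tissue against wild type ligament. Of 3801 values of named genes under alternatives, 1950 moved by less than the spot noise, 1850 moved by more and 1 reversed. The 1148 values of gene lists were list medians and the counts of lists in those outer 2.5%. Of these, 936 stayed within their spread, or for counts within a ratio of 1.5, 207 moved by more and 5 reversed. Reversed means a change of sign of a gene past 2-fold or of a list in those outer 2.5%, so sign changes of other genes and lists are not counted in it. Except where the construction is named, the cause was not tested. On an array 49.0% to 56.3% of spots were well above background, and genes on the others have a bound or no value.

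By construction a 4-fold threshold gave fewer genes: 484 higher and 678 lower in tissue against stem cells, 184 and 264 in transgenic against wild type ligament, 3963 and 2000 in wild type ligament against stem cells, 1745 and 3908 in tissue against wild type ligament, and 7 higher and 15 lower in both the first and second of these comparisons. An 8-fold definition put the share of ligament-high genes lower in the tissue at 4.51%.

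With normexp, 1075 genes were higher in tissue against stem cells, and 408 were higher and 570 lower in transgenic against wild type ligament, with 24 higher and 88 lower in both. The share nearer to ligament was 39.6%, ligament-high genes were 10.8% higher and 4.75% lower, and stem cells and transgenic ligament correlated at 0.770. The spot SD was 0.147 in the tissue and 0.151 in wild type ligament. Egr2 in wild type ligament against stem cells turned to 0.049, and the chemokine median in tissue against wild type ligament to -0.53.

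The median over genes well above background on both arrays moved with quantile normalization. It moved by -0.28 in wild type ligament against stem cells and by 0.41 in tissue against wild type ligament. Centring moved these medians by 0.17 and -0.20. The share nearer to ligament was 50.2% with quantile normalization, 48.3% with centring, 50.2% with the deposited value table and 50.04% with transgenic ligament as the reference. Ligament-high genes lower in the tissue were 4.32%, 7.22% and 4.63% in the first 3 of these, and the deposited table gave 18.5% higher.

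Only genes well above background on every array gave 669 genes higher in transgenic against wild type ligament, 54 higher in both comparisons, and ligament-high genes 21.9% higher and 7.61% lower. The chemokine median turned to -0.29 in tissue against wild type ligament and 1.31 in wild type ligament against stem cells. With no filter and no bound, which by construction adds dim genes, the counts were 2973 higher and 3542 lower in tissue against stem cells and 2125 and 2128 in transgenic against wild type ligament. They were 17158 higher in wild type ligament against stem cells, 17565 lower in tissue against wild type ligament, and 313 higher and 388 lower in both. Ligament-high genes were 18.4% higher and 7.32% lower, the share nearer was 52.0%, and the chemokine medians were -2.20 and 1.67. Stem cells then correlated at 0.845 with transgenic and 0.833 with wild type ligament, and the tissue at 0.847 and 0.834. The mean of all probes gave 5.42% of ligament-high genes lower.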

Other observations

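The tests of explanations in this part were chosen after the result was seen. Of the detected Hox genes, which set position along the body, 14 of 21 were higher in wild type ligament than in stem cells and 5 lower (median 4.55, or 3.17 with dim genes at their bound), with bounds of 7.56 for Hoxd8 and 7.36 for Hoxc10. Over the 6 genes well above background on both arrays the median was 0.06, at percentile 50.2. In the tissue against wild type ligament the Hox median was -4.77, or -0.42 at percentile 48.3 over the 8 genes well above background on both arrays. Against stem cells it was -0.26, or 0.00 with no filter, and in transgenic against wild type ligament 0.44, or 0.11 at percentile 87.7 with normexp. Imprinted growth genes had medians of -0.59 in tissue against stem cells, 0.54 in transgenic against wild type ligament, -0.42 in wild type ligament against stem cells and -0.99 in tissue against wild type ligament. The third turned to 0.59 with no filter and the last to 1.89 over genes well above background on both arrays. Cdkn1c, an inhibitor of cell division, was higher by 7.54 in wild type ligament than in stem cells and Mest lower, at -5.48. Antigen presentation genes had medians of -0.09, 0.10, 0.47 and -0.70 in the same order of comparisons, of which the first turned positive with quantile normalization and the third to -0.40 over genes well above background on both arrays. H2-Ab1 had a bound of 8.74 in wild type ligament against stem cells. Wnt pathway genes had medians of 0.40, 0.01, 0.35 and -0.04, with Dkk3 higher by 2.14 in the tissue and by 1.11 in transgenic ligament; the first turned negative with normexp, the second with centring, and the last pair changed sign with quantile normalization. Heat shock genes had medians of 0.14, 0.10, -0.09 and -0.32, with Hspb1 at 9.87 in wild type ligament against stem cells; the third changed sign with centring and the last with quantile normalization.

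Chemokine and cytokine genes had a median of 0.28 in the tissue against stem cells, where Cxcl12 (-2.19) and Il6 (-2.04) were lower and Cxcl5 (1.66) higher, -2.46 in wild type ligament against stem cells and 1.33 in tissue against wild type ligament, where the last pair reversed, to 1.31 and -0.29, over genes well above background on both arrays. Nerve sheath genes had medians of 0.15, -0.16, 1.19 and -1.15 in the order above, and pluripotency genes 0.11, -0.01, 2.44 and -2.56, where Tdgf1 was higher in wild type ligament by 6.43 and the value of -0.01 turned positive with quantile normalization. With normexp the first values turned to -0.06 and -0.14, and the second nerve sheath value turned to 0.01 with the mean of all probes. Of 5 sex-linked genes only Xist was well above background, and it was so on every array. Its log2 differences were 0.24, 1.06, -1.37 and 1.61 in the order above. Metalloproteinases and their inhibitors had a median of -0.17 in the tissue against stem cells, or 0.20 over genes well above background on both arrays, with the inhibitor Timp1 at -3.46 and Mmp14 at 1.58. Periodontal ligament markers had -0.54 there and 0.47 in transgenic against wild type ligament, with Postn at 1.28 in the tissue. Other matrix collagens had -0.16, cartilage markers 0.04, bone markers 0.18, smooth muscle genes -0.69, endothelial genes -0.67, lymphoid genes -0.25, neutrophil genes 0.05, erythroid genes -1.17, epidermal genes -0.45 and oxidative phosphorylation genes -0.21 in the tissue against stem cells; the collagen and oxidative phosphorylation medians turned positive with quantile normalization. The cartilage median turned to -0.06 with normexp, the bone median to -0.16 with the mean of all probes, and the erythroid median to 0.02 with no filter. Prg4, the joint lubricant, had a bound of -3.36 and Cnmd was higher by 3.01. In transgenic against wild type ligament elastic fibre genes had a median of 0.28, basement membrane genes 0.24, TGF-beta targets 0.22, stromal markers 0.17, macrophage genes -0.27, glycolysis genes -0.07 and oxidative phosphorylation genes -0.24, of which the last pair turned positive with quantile normalization.

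A common response to gene A in cells and animals may appear as genes changed the same way in both comparisons. Of 544 genes past 2-fold in both, 286 moved the same way (52.6%, exact interval 48.3% to 56.8%), and independent lists give 50.1%, which lies inside the interval. The tendon and ligament list, which such a response could raise in both, had a median of -0.65 in the tissue, where random lists had an SD of 0.261, but this value moved to -0.06 over genes well above background on both arrays. Cell cycle genes lay in the lower tail of random lists in both comparisons (medians -2.87 and -0.64). Unfolded protein response genes lay in the upper tail in both (0.34 and 0.79). Each stayed there in all 8 settings. Small leucine-rich proteoglycans also lay in the upper tail (0.44 and 1.34), but in the tissue in 6 of 8 settings. The cholesterol, collagen processing, interferon and tendon lists lay in opposite tails. None of these values decides, and the arrays hold no transfection with an empty plasmid.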
